A study of Arabidopsis thaliana with 4 samples.

How the data were processed

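RNA was sequenced from whole Arabidopsis seedlings, 14 days old, of the mutants hdp3-2 and asil1-2, with 2 libraries per mutant, and compared by the authors with the wild-type strain Col-0. Per the labels, seeds were kept for 3 days at 4 °C and grown at 22 °C under 16 h of light and 8 h of dark on agar plates (0.8%) that contained sucrose at 2%, and total RNA was taken from 100 mg of tissue. The labels do not say whether RNA with a poly(A) tail was selected.

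The authors named TopHat2, Cufflinks, Cuffdiff and deepTools and the genome build TAIR10 in their processing notes, without versions or options. They deposited 2 tables in the column layout of Cuffdiff, 1 per mutant. The FPKM values, fragments scaled to transcript length and library size, were made by the authors with 1 value per genotype, combined over libraries and scaled within each table. The wild-type FPKM columns of the deposited tables differ by a factor of 0.982, and 99.97% of 23185 genes lie within 0.1% of it, so each table was scaled on its own. The score deposited per gene is the authors' test statistic, 0 where they made no test. The p-value and q-value columns hold the authors' p and their q after correction over the tested genes, per the file headers. The smallest p in the deposited tables is 5e-05.

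No table holds counts or values per library, so the depth is unknown and no test between libraries was run here. A gene was called where its test status was OK and the authors' q was under 0.05. The p-values measure only the spread between these samples, which may be technical. The log2 fold change was computed from the FPKM columns, since the fold column of the tables was damaged in part by spreadsheet software, and its standard error is the fold change divided by the authors' statistic. The z value that the authors' p implies was compared with their statistic over genes with a statistic from 0.3 to 3 in size. At the median it was 1.41 times the statistic in the hdp3-2 table and 1.42 times in the asil1-2 table. A standard error behind p would be smaller for most of these genes, but not for every gene. No fold is given for genes listed at 0 in a genotype.

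The overlap of calls was tested with Fisher's exact test, two-sided, over the 20010 genes tested in both tables. Because wild type is shared, 1000 simulations of unchanged mutants were run in which the control gave 0.5 of the smaller variance. The correlation was taken across genes with FPKM of at least 1 in some genotype and above 0 in all. The difference between the mutants was tested per gene with a z test, SE being the root of the summed squares, with Benjamini-Hochberg adjustment. It was tested on simulated data with 200 changed genes, where a true log2 difference of 2 was recovered in 64.5% and a difference of 4 in 91.5%, with 0 false calls. With the summed variance multiplied by 0.5, 23 and 17 false calls were made.

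The gene lists, 22 in number with 377 members, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Of 376 loci in the lists, 375 are in the tables. Higher and lower calls of each list were tested against all other tested genes with Fisher's exact test, two-sided, adjusted by Benjamini-Hochberg over 88 tests. Each list was also adjusted over the list alone. As planned, the median log2 fold change of each list was placed as a percentile among 10000 random lists. These had the same size and were matched on mean expression. Random lists treat the members as independent, so the percentile is given without a p-value. The rule for named genes took, per comparison, the targeted genes, the 8 largest increases and 8 largest decreases among called genes with FPKM above 0 in both genotypes and at least 1 in the higher, and the 3 called genes with the highest FPKM among those listed at 0 in the other genotype. It added the 4 most changed called members of each list that was enriched or had at least 3 calls, and of the seed, trihelix, flowering time and Harbinger lists whatever the test. For the overlap it took 8 genes called in the same direction and 4 in opposite directions, and for the difference 5 on each side.

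Alternatives were a q under 0.01, a minimum log2 fold change of 1, an FPKM minimum of 1 or 10, a recomputed adjustment, pseudocounts of 1 and 0.1, centring on the median, and leaving out organelle genes. Added after seeing the data were a normal reading of the statistic and leaving out the heat shock, clock and touch lists. The pseudocount of 1 and the centring were also added then for the values of the named genes. Positions are counted from 1 in TAIR10. Of 33557 loci, 32809 have an entry in the reference annotation, and 4249 genes share a locus span with another gene, so their values are less certain. Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.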

Results

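RNA was profiled by sequencing in whole seedlings of Arabidopsis thaliana, 14 days old, of the mutants hdp3-2 and asil1-2, with 2 libraries for each mutant. The authors compared them with the wild-type strain Col-0. The series asks whether HDP3, a Harbinger transposase that the plant has taken over as a host protein, and ASIL1, a trihelix DNA-binding factor, affect the transcription of overlapping sets of genes. The authors' deposited tables compare each mutant with wild type over 33557 genes and hold 1 FPKM value per gene and genotype, with a test statistic, a p and a q, and no values per library. Sequencing depth is therefore unknown here, and the spread between libraries enters only through the authors' statistic. The wild-type libraries are not among the samples of this series, and their number and day of harvest are not given in the sources used here. The labels cover the mutants only, so the age, tissue and growth conditions of the wild-type plants are not given either. Nothing in the labels says whether the libraries of a mutant came from separately grown plants, so the authors' p-values measure only the spread between these samples, which may be technical. A gene is said to be called, or to have risen or fallen, where the authors' q was under 0.05. Log2 fold changes were computed from the deposited FPKM values and stand with a standard error (SE) derived from the authors' statistic.

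The level of the targeted gene was compared first, to check the labels. ASIL1 (AT1G54060) was 5.50-fold lower in the asil1-2 seedlings than in wild type. In the authors' deposited table its level was 4.16 FPKM in asil1-2 and 22.9 FPKM in wild type, with a q of 0.00165 in their Cuffdiff test. The log2 fold change of ASIL1 in asil1-2 was -2.46 ± 0.30 (SE). In hdp3-2 the authors' deposited table gave 27.8 FPKM against 22.5 FPKM, a q of 0.598, and the log2 fold change was 0.30 ± 0.29 (SE). The gene lies on chromosome 1 from 20180679 to 20182324 in TAIR10, with positions counted from 1. Neither the tables nor the reference gene names used here pair the name HDP3 with a locus, so the level of the HDP3 transcript is not reported, and the hdp3-2 label has no such check.

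The comparison of hdp3-2 with wild type asks which genes depend on HDP3. In hdp3-2 the 8 genes with the largest increases were all heat shock or chaperone-related genes. HSP17.6A (AT5G12030), a small chaperone, rose by 7.26 ± 0.94 (SE) in log2, the small heat shock protein gene AT1G07400 by 5.78 ± 0.58, HSFA2 (AT2G26150), a transcription factor of the heat response, by 4.85 ± 0.43, and the chaperone HSP90.1 (AT5G52640) by 4.15 ± 0.31. The call of HSP17.6A was close to the threshold, with a q of 0.0441 in the authors' Cuffdiff test and 0.592 FPKM in wild type. Its Cuffdiff p of 0.0013 is larger than its statistic of 7.68 implies, so its SE may be too small. The authors' deposited table lists HSP90.1 at 5.61 FPKM in wild type and 99.5 FPKM in hdp3-2. HSP101 (AT1G74310) rose by 3.94 ± 0.33 and HSP70 (AT3G12580) by 2.83 ± 0.29. Of the 14 members of the heat shock list that were tested, 8 rose and 0 fell, where the share of higher calls among all genes would give 0.182 (Fisher's exact test, two-sided, adjusted p = 1.85e-10). Adjusted over the list alone, the same number, 8, rose. Of the 6 members that did not pass, 5 had log2 fold changes from 3.86 to 6.85 and HSP18.2 (AT5G59720), chosen after its value was seen, had -0.23 ± 0.53. The remaining genes among the 8 largest increases were AT1G59860 and AT2G29500, both of the HSP20-like chaperone family, and FKBP65 (AT5G48570), a peptidyl-prolyl isomerase, at 4.102 ± 0.56, 3.77 ± 0.37 and 3.65 ± 0.31. The chaperone gene AT1G71000, of the DnaJ family, was listed at 0 in wild type and at 13.99 FPKM in hdp3-2 in the authors' deposited table.

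Clock genes moved in both directions in hdp3-2. Of 24 members tested, 4 rose (adjusted p = 0.00307) and 7 fell (adjusted p = 3.12e-06), both by Fisher's exact test, and adjusted over the list alone 6 rose and 10 fell. LNK3 (AT3G12320) had a log2 fold change of -1.46 ± 0.29 and RVE1 (AT5G17300) of -1.22 ± 0.29. The core clock genes CCA1 (AT2G46830, -0.94 ± 0.32) and LHY (AT1G01060, -0.98 ± 0.30), which peak around dawn, were chosen after their values were seen. FKF1 (AT1G68050), a blue-light receptor, rose by 1.75 ± 0.49, CCR2 (AT2G21660), a clock-controlled RNA-binding protein gene, by 1.36 ± 0.29, and PRR5 (AT5G24470), a clock repressor, by 1.24 ± 0.30.

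Glucosinolate genes fell in hdp3-2, with 5 of 17 tested members lower and 0 higher (Fisher's exact test, adjusted p = 0.000132), and 9 lower when adjusted over the list alone. MYB29 (AT5G07690), a regulator of the aliphatic branch, fell by 1.89 on the log2 scale (SE 0.39), and CYP79F1 (AT1G16410), the enzyme at the entry of that branch, fell by 1.88 (SE 0.30). CYP83A1 (AT4G13770) and MYB28 (AT5G61420) had log2 fold changes of -0.88 ± 0.28 and -0.87 ± 0.31. Of 24 jasmonate and ethylene defence genes, 4 fell and 0 rose (exact test, adjusted p = 0.00867), and 4 fell and 1 rose adjusted over the list alone. They were JAZ5 (AT1G17380, -1.82 ± 0.57), CORI3 (AT4G23600, -1.46 ± 0.43), AOS (AT5G42650, -1.40 ± 0.27), which makes a jasmonate precursor, and MYC2 (AT1G32640, -0.78 ± 0.28). By the same exact test the enrichment of this list ended at a q under 0.01 (adjusted p = 0.160), and that of the glucosinolate list with a 2-fold minimum (adjusted p = 0.0527).

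Of 15 touch, wound and handling genes, 3 rose in hdp3-2 (exact test, adjusted p = 0.00867) and 1 fell, and 4 rose and 2 fell adjusted over the list alone. CML38 (AT1G76650) and TCH3 (AT2G41100), which encode calcium-binding proteins, rose by 1.17 ± 0.37 and 0.89 ± 0.29, and WRKY18 (AT4G31800) by 0.72 ± 0.28, while TCH2 (AT5G37770) had a log2 fold change of -0.68 ± 0.28. With a 2-fold minimum the enrichment was lost (exact test, adjusted p = 0.471). Among the 25 trihelix genes, ASIL2 (AT3G14180), a relative of ASIL1, and AT2G44730 rose by 0.86 ± 0.29 and 0.82 ± 0.29, without enrichment (exact test, adjusted p = 0.245), and adjusted over the list alone 4 rose and 1 fell. The flowering repressor SNZ (AT2G39250) was the 1 flowering time gene called of 21 tested, at -1.45 ± 0.35 (exact test, adjusted p = 0.953), and adjusted over the list alone 1 rose and 3 fell.

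Organelle genes form no fixed list, and their enrichment was not tested. Of 59 plastid genes tested in hdp3-2, 15 rose and 0 fell, beside 246 of 20094 nuclear genes that rose, and 53 of the 55 plastid genes with FPKM above 0 in both genotypes had a positive log2 fold change, with a median of 0.95. Of 24 mitochondrial genes, 2 rose, 23 had a positive value, and the median was 1.69. In asil1-2, 0 of 58 plastid and 0 of 16 mitochondrial genes were called by the authors' Cuffdiff test, and 6 and 0 had an unadjusted p under 0.05. Over the 54 plastid and 15 mitochondrial genes tested in both tables with FPKM above 0 throughout, the medians were 0.93 and 1.61 in hdp3-2 and 0.13 and 0.09 in asil1-2. In the z test of the difference between the mutants 0 plastid and 0 mitochondrial genes passed, and 4 and 2 passed with the summed variance multiplied by 0.5. Single organelle genes are therefore not shown to differ between the mutants. That z test was conservative, as given below, and the gap between the medians was not tested, so it stays open. The plastid genes PSBH (ATCG00710) and RPL33 (ATCG00640) were listed at 0 in wild type and at 12.3 and 23.62 FPKM in hdp3-2 in the authors' deposited table. In asil1-2 they were also above the wild-type 0, at 3.41 and 6.04 FPKM, and were not called. The FPKM values of all genes sum to 4.47e+06 in hdp3-2 and 1.46e+06 in wild type in the authors' deposited table, and to 1.40e+06 and 1.48e+06 in that for asil1-2. The highest FPKM in hdp3-2 in the authors' deposited table was 1.24e+06, in the plastid gene RPS12 (ATCG00065), which was listed at 0 in wild type, was not tested and was chosen after its value was seen.

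The largest decrease in hdp3-2 was in AT3G19120, annotated as a transposase of the PIF and Ping-Pong family, the group that holds the Harbinger elements. The authors' deposited table lists it at 15.8 FPKM in wild type and 0.968 FPKM in hdp3-2 (q = 0.00374), and the log2 fold change of AT3G19120 was -4.03 ± 0.50 (SE). It lies on chromosome 3 from 6609412 to 6611059 in TAIR10. The next were the noncoding RNA gene AT1G67105 (-3.62 ± 0.81), TAT3 (AT2G24850), a tyrosine aminotransferase (-3.53 ± 0.78), AT2G30766 (-3.08 ± 0.54) and the cysteine protease gene AT2G27420 (-2.83 ± 0.61). AT1G47395, AT4G33550 and AT5G66740 had values of -2.69, -2.37 and -2.36. Of the 7 genes on the list of Harbinger-derived genes and their partners, 0 were called in hdp3-2 by the authors' Cuffdiff test and 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05.

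In all, 622 of 20177 tested genes were called in hdp3-2 from the authors' deposited table, of which 263 rose and 359 fell. At least a 2-fold change was seen in 128 of those that rose and 146 of those that fell, or in 145 and 128 after the median log2 fold change of -0.07 was subtracted. For most genes with a statistic from 0.3 to 3 in size, the authors' p was smaller than a standard normal reading of that statistic gives. The normal reading, chosen after seeing the data, called 147 genes. Of the 25 seed storage and late maturation genes and 17 seed maturation regulators on the lists, only 9 and 7 were tested in hdp3-2. Of these, 0 of either list were called by Cuffdiff, with 2 and 0 genes at an unadjusted p under 0.05. The other members had no test, so they say nothing about a change. The floral homeotic and silencing reporter lists, of 15 and 4 genes, also had few tested members. No member was called in the lists of floral homeotic genes (5 tested, 0 at an unadjusted p under 0.05), DNA methylation machinery (22 and 0), silencing reporter loci (1 and 0), Polycomb and trithorax proteins (14 and 1), salicylic acid defence (16 and 4), nuclear photosynthesis (28 and 1), root markers (12 and 2), anthocyanin synthesis (14 and 2) and auxin response (8 and 2). Adjusted over the list alone, 2 salicylic acid genes and 1 anthocyanin gene fell, and 0 genes of the other lists without a call passed. The iron deficiency list (11 tested) and the abscisic acid and cold list (19 tested) each had 1 gene higher and 1 lower, and the phosphate starvation list (8 tested) had 1 higher, none of them enriched (exact test, adjusted p from 0.462 to 0.909). Adjusted over the list alone, 1 iron gene rose and 5 fell, 2 abscisic acid and cold genes rose and 5 fell, and 1 phosphate gene rose and 1 fell. Among the lists without enrichment in hdp3-2, the iron median of -0.42 lay at percentile 0.37 of random lists. The root marker median of 0.20 lay at percentile 99.4, and the other such lists lay from 4.78 to 95.79.

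**Figure D1:**
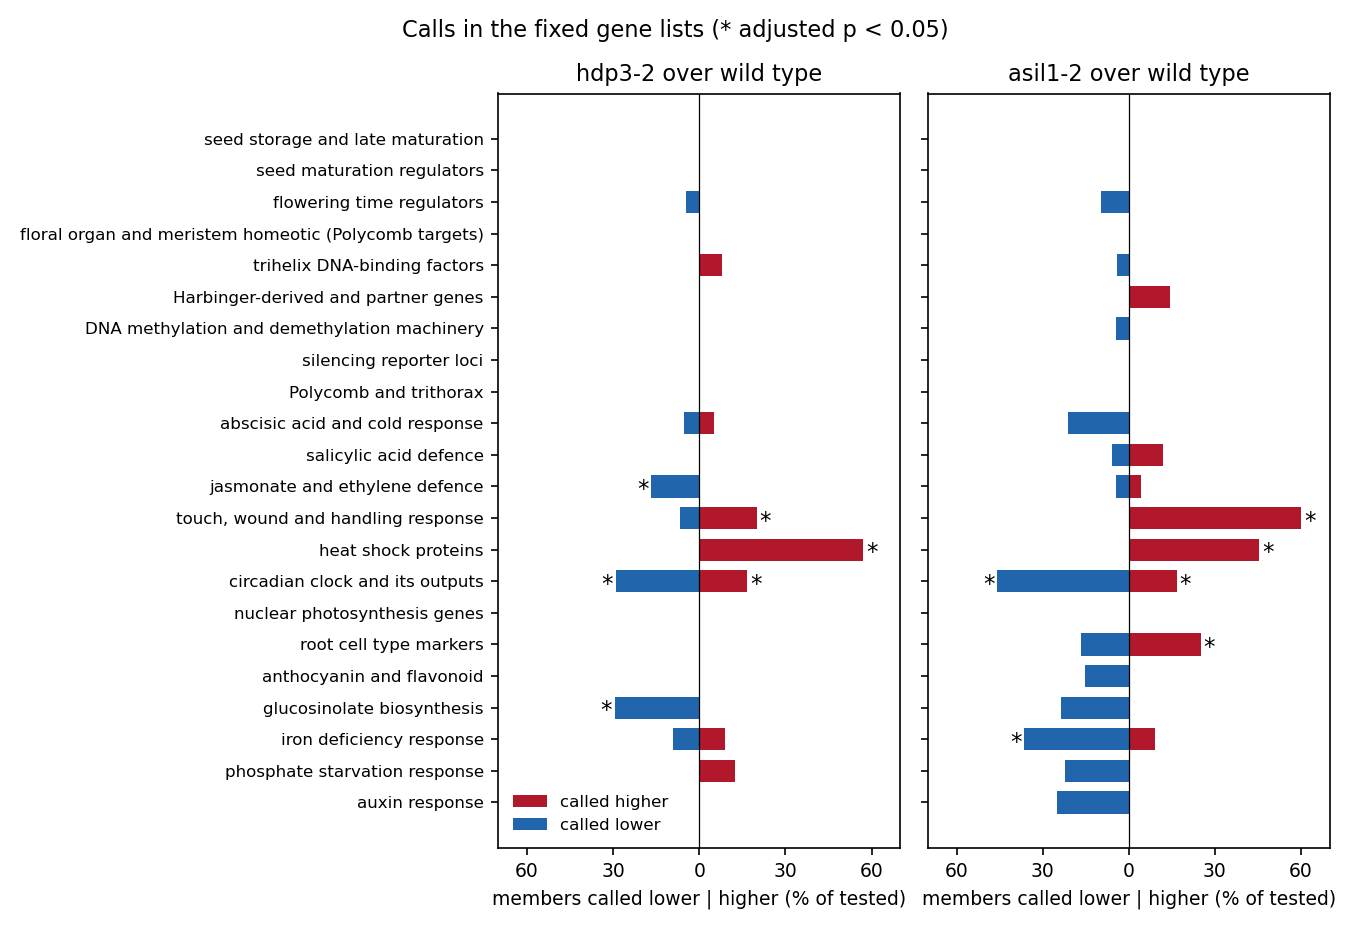
Share of the tested members of each gene list that was called higher (red, to the right) or lower (blue, to the left) than wild type in hdp3-2 (left panel) and asil1-2 (right panel), as a percentage on both horizontal axes, with stars for an adjusted p under 0.05 in Fisher's exact test. The heat shock list leads in hdp3-2, with 8 of 14 members higher, and the touch, wound and handling list in asil1-2, with 9 of 15 higher.

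The comparison of asil1-2 with wild type asks which genes depend on ASIL1. In asil1-2 the genes that respond to touch, wounding and handling had the largest share of members that rose among the fixed lists. Of 15 tested, 9 rose and 0 fell, against 0.406 from the share of higher calls among all genes (Fisher's exact test, two-sided, adjusted p = 1.39e-09), and 10 rose and 1 fell adjusted over the list alone. ZAT10 (AT1G27730), a zinc finger repressor, rose by 2.11 ± 0.31 (SE) in log2, CML38 by 1.82 ± 0.32, SIB1 (AT3G56710) by 1.60 ± 0.41 and ERF105 (AT5G51190), an ethylene response factor, by 1.45 ± 0.33. Of 11 heat shock genes tested, 5 rose and 0 fell (exact test, adjusted p = 0.000101), and adjusted over the list alone 5 rose. HSP17.6A rose by 3.42 ± 0.99 (q = 0.0373 in the authors' Cuffdiff test), AT1G07400 by 2.21 ± 0.59, HSFA2 by 1.45 ± 0.43 and HSP101 by 1.07 ± 0.30.

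The clock list held 11 genes that fell (exact test, adjusted p = 7.46e-07) and 4 that rose (adjusted p = 0.0269) among 24 tested in asil1-2, and adjusted over the list alone 11 fell and 7 rose. CDF1 (AT5G62430), a repressor of photoperiodic flowering, had a log2 fold change of -1.60 ± 0.26, LNK3 of -1.57 ± 0.26, and RVE1 of -1.36 ± 0.25, whereas FKF1 rose by 1.42 ± 0.46. The enrichment of higher calls, but not of lower ones, was lost at a q under 0.01 (exact test, adjusted p = 0.285) and with a 2-fold minimum (adjusted p = 0.839).

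Of 11 genes on the iron deficiency list, 4 fell and 1 rose in asil1-2 (exact test, adjusted p = 0.0223 for the lower calls), and 6 fell and 1 rose adjusted over the list alone. The transcription factors bHLH38 (AT3G56970) and bHLH101 (AT5G04150) had log2 fold changes of -2.10 ± 0.74 and -1.49 ± 0.53, AT1G47395 of -2.26 ± 0.65 and BTS (AT3G18290), a regulator of the iron response, of -0.69 ± 0.25. The member that rose, chosen after its value was seen, was FER1 (AT5G01600), which encodes the iron store ferritin, by 0.66 ± 0.24, and FER2 (AT3G11050), another ferritin, was among the 8 largest increases at 2.79 ± 0.48. At a q under 0.01 the enrichment of lower calls was lost (exact test, adjusted p = 0.270). On the list of root markers 3 of 12 rose (exact test, adjusted p = 0.0269) and 2 fell, and adjusted over the list alone 3 rose and 2 fell. The nitrate transporter gene NRT2.1 (AT1G08090) rose by 1.51 ± 0.28 and PRP1 (AT1G54970), a root hair wall protein gene, by 1.13 ± 0.41, while the iron uptake genes FRO2 (AT1G01580) and IRT1 (AT4G19690) had values of -1.71 ± 0.47 and -1.03 ± 0.47. The root list lost its enrichment with a 2-fold minimum (exact test, adjusted p = 0.0515).

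Glucosinolate genes were lower in asil1-2 in 4 of 17 cases, which did not pass the correction (exact test, adjusted p = 0.0940), with 7 lower adjusted over the list alone. These 4 were MYB29 (-1.29 ± 0.32), MYB28 (-1.15 ± 0.28), CYP79F1 (-1.01 ± 0.25) and CYP83A1 (-0.66 ± 0.24). Of 19 abscisic acid and cold response genes 4 fell (exact test, adjusted p = 0.130), among them RAB18 (AT5G66400), a dehydrin, at -0.98 ± 0.25, and P5CS1 (AT2G39800), a proline synthesis enzyme, at -0.95 ± 0.25. LTI30 (AT3G50970) and RD22 (AT5G25610) had values of -0.68 ± 0.24 and -0.65 ± 0.24. Adjusted over the list alone 6 of these genes fell. In the salicylic acid list SARD1 (AT1G73805) and WRKY70 (AT3G56400) rose by 1.39 ± 0.49 and 0.79 ± 0.25 and PBS3 (AT5G13320) had a value of -0.75 ± 0.34 (17 tested, exact test, adjusted p = 0.394 for the higher calls), and adjusted over the list alone 2 rose and 2 fell.

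ATSPS4F (AT4G10120), a sucrose-phosphate synthase gene on chromosome 4 from 6314787 to 6319936 in TAIR10, had the largest decrease in asil1-2. The authors' deposited table lists it at 66.5 FPKM in wild type and 5.75 FPKM in asil1-2 (q = 0.00165), and the log2 fold change of ATSPS4F was -3.53 ± 0.25 (SE). AT5G66740 (-3.33 ± 0.90), AT2G27420 (-3.11 ± 0.60), the F-box gene AT4G34550 (-2.94 ± 0.77), AT2G30766 (-2.92 ± 0.50), the terpene synthase gene TPS03 (AT4G16740, -2.85 ± 1.00), AT2G15020 (-2.67 ± 0.34) and AT2G14247 (-2.63 ± 0.78) followed. The increases were led by AT5G28335 (4.15 ± 0.85), which reached 1.02 FPKM in asil1-2 in the authors' deposited table, HSP17.6A and AT3G22235 (3.31 ± 0.74), annotated as a stress tolerance protein. The acyltransferase gene AT2G25150, the ERF-type gene AT1G33760, LURP1 (AT2G14560), a pathogen-response gene, and ERF13 (AT2G44840) rose by 2.99 ± 0.61, 2.86 ± 0.58, 2.67 ± 0.55 and 2.62 ± 0.73. Of the called genes listed at 0 in 1 genotype, the authors' deposited table gave AT1G11362 1.17 FPKM and AT5G62330 0.990 FPKM in asil1-2 with wild type at 0, and the histone gene AT1G75600 at 0 in asil1-2. AT1G11362 was also called in hdp3-2, at 0.527 FPKM.

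In total 1702 of 20205 tested genes were called in asil1-2 from the authors' deposited table, 547 higher and 1155 lower. At least a 2-fold change was seen in 197 and 256 of them. After the median log2 fold change of -0.08 was subtracted, the 2-fold calls split into 240 higher and 199 lower, while all calls together stayed at 547 higher and 1155 lower. The median change among calls was 1.70-fold, so a shift this small could hardly turn their direction, and the unchanged split shows no stability. The normal reading of the authors' statistic, chosen after seeing the data, called 438 genes. Of the Harbinger-derived genes and partners, AT4G29780, annotated as a nuclease, rose by 1.04 ± 0.27 (7 tested, exact test, adjusted p = 0.657), and 1 rose adjusted over the list alone. In the flowering time list SNZ and the repressor SVP (AT2G22540) were lower, at -0.84 ± 0.29 and -0.58 ± 0.24 (21 tested, exact test, adjusted p = 0.996), and among the 25 trihelix genes ASIL1 itself was the 1 call. Adjusted over the list alone, 2 flowering time genes and 1 trihelix gene fell. Of 25 seed storage and late maturation genes and 17 seed maturation regulators, only 9 and 7 were tested in asil1-2. Of these, 0 were called by Cuffdiff, with 2 and 1 at an unadjusted p under 0.05. The untested members say nothing about a change. No call was made among the floral homeotic genes (6 of 15 tested, 1 at an unadjusted p under 0.05) and silencing reporter loci (1 of 4 and 1). The Polycomb and trithorax proteins (14 and 3) and nuclear photosynthesis genes (28 and 0) also had none. Of the lists without a call, 0 genes passed when adjusted over the list alone, leaving aside the silencing reporter list. With 1 tested member, QQS (AT3G30720), that list has no correction of its own. QQS had a log2 fold change of -1.10, with p = 0.0349 and q = 0.202 in the authors' Cuffdiff test. Of the DNA methylation machinery 1 of 22 fell, of the jasmonate and ethylene list 1 of 23 rose and 1 fell, and 2 members each fell of the anthocyanin (13 tested), phosphate starvation (9 tested) and auxin (8 tested) lists (exact test, adjusted p from 0.394 to 1). Adjusted over the list alone, 1 DNA methylation gene fell, 2 jasmonate and ethylene genes rose and 1 fell, and 3 anthocyanin, 2 phosphate and 2 auxin genes fell. Among the lists without enrichment in asil1-2, the anthocyanin median of -0.53 lay at percentile 0.03 of random lists. The glucosinolate median of -0.29 and the auxin median of -0.37 lay at percentiles 1.29 and 1.97. The other such lists lay from 3.28 to 77.71.

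**Figure D2:**
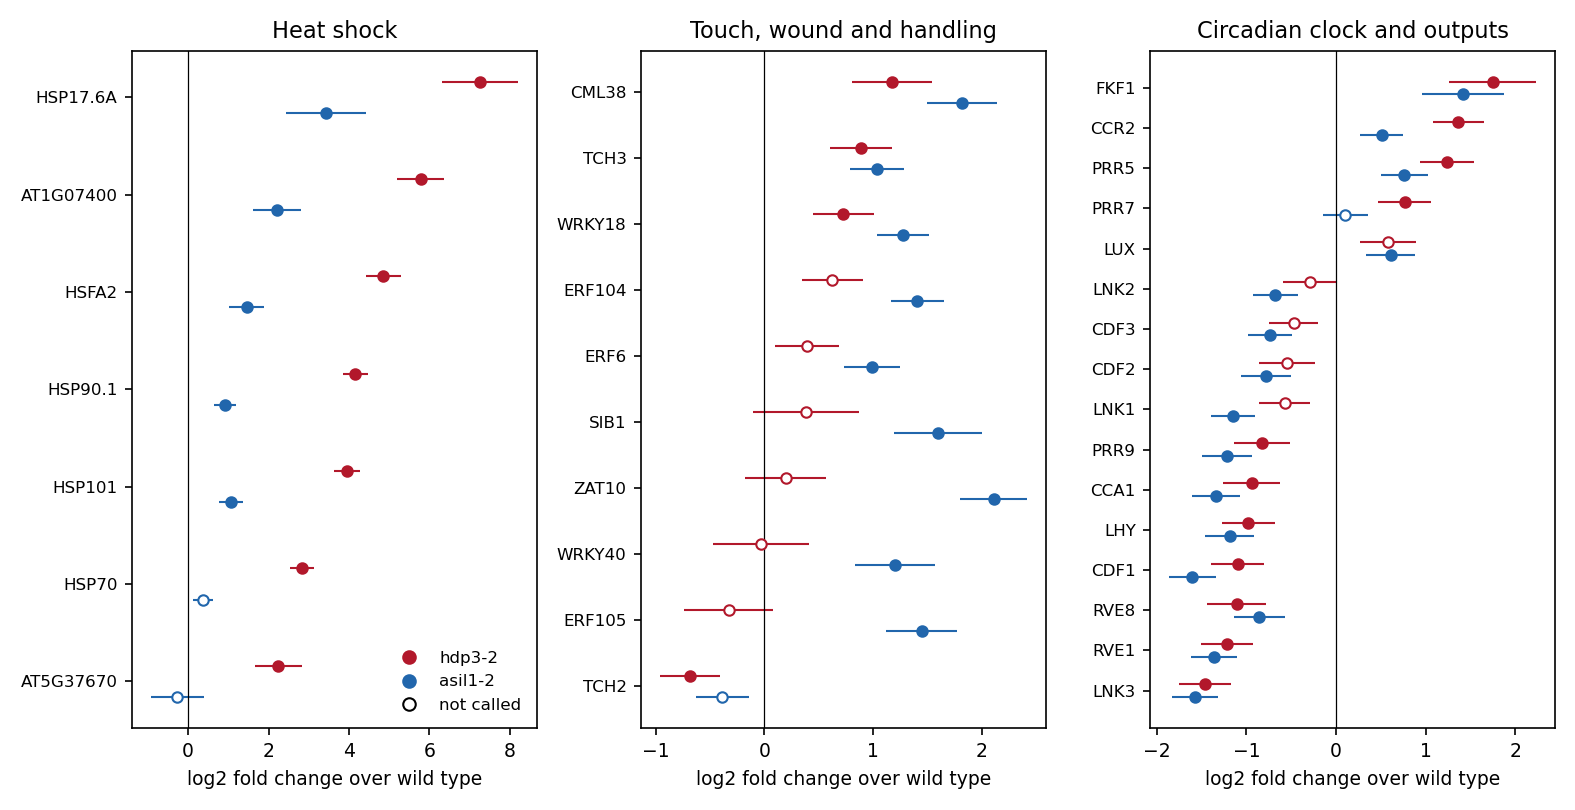
Log2 fold change over wild type, on the horizontal axes, of the heat shock genes (left), touch, wound and handling genes (middle) and clock genes (right) that were called in at least 1 mutant and had FPKM above 0 in every genotype. Red points are hdp3-2 and blue points asil1-2, filled where called, and bars are the SE derived from the authors' statistic. The heat shock genes stand higher in hdp3-2, and HSP90.1 is at 4.15 there and at 0.92 in asil1-2.

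To ask whether the effects overlapped, the calls were compared over the 20010 genes tested in both tables. The same direction was shared by 351 genes and opposite directions by 6. Of 258 genes called higher in hdp3-2, 116 were also higher in asil1-2, where independent lists of these sizes would share 6.98 (Fisher's exact test, two-sided, p = 8.67e-114). Of 359 called lower in hdp3-2, 235 were also lower in asil1-2, where independent lists would share 20.7 (exact test, p = 9.35e-206). The exact test treats the comparisons as independent, which their shared wild type breaks, so these p-values do not measure a shared effect. The shared genes were 56.9% of the hdp3-2 calls and 20.7% of the asil1-2 calls.

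Among the shared genes, the rule for the largest change common to the mutants named 3 genes that rose and 5 that fell. HSP17.6A and AT1G07400 rose with the values above, and MIOX2 (AT2G19800), an inositol oxygenase, rose by 2.66 ± 0.29 in hdp3-2 and by 2.26 ± 0.25 in asil1-2. The authors' deposited table for hdp3-2 lists MIOX2 at 52.9 FPKM in wild type and 334 FPKM in the mutant. The genes that fell were AT2G30766, AT2G27420, AT1G67105, AT5G66740 and AT1G47395, and the values of AT1G67105 were -3.62 in hdp3-2 and -2.50 in asil1-2. Of the clock list, 10 genes were called in both mutants, and all 10 had the same direction in both, which the shared wild type alone favours, since simulated unchanged mutants shared 0.629 genes in opposite directions on average against 155 in the same.

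Because the comparisons share their wild-type libraries, they share part of their error. In 1000 simulations of mutants without any effect, with a control that contributed 0.5 of the smaller variance, gene lists of the observed sizes shared 155 genes in the same direction on average and 195 at most, against 349 observed over the 19267 genes simulated. The share of 0.5 was assumed and not varied, so 195 is a bound for that share only. The simulated number leaves out real effects and the number for independent lists leaves out the shared control, so neither difference measures a shared effect. The wild-type libraries could not be split, since the tables hold no values per library, and part of the overlap may come from them. With the normal reading of the authors' statistic 70 genes were shared in the same direction, where independent lists would share 1.57, and 0 in opposite directions. No simulation shared more than 1 gene under that reading, which is not the rule behind the 349. That reading calls hardly any gene in mutants without an effect, so the low number was fixed in advance. It does not measure what the shared control adds.

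Across 19320 genes with FPKM of at least 1 in some genotype, the log2 fold changes of the mutants had a Pearson's r of 0.53 and a Spearman's rho of 0.49. This is a correlation across genes, which are not independent replicates. Over the 19267 genes simulated, the observed r was 0.54, and simulated unchanged mutants gave 0.20 to 0.58 with a mean of 0.42. That range is wide, so lying within it does not show that the shared wild type explains the correlation. The share of genes with the same sign in both mutants was 67.9%, against 64.5% on average in the simulations. The observed covariance over these genes was 0.113. The simulated covariance was 0.121 on average with the standard errors from the authors' statistic and 0.0608 with those that their p implies, so the difference from the observed one was -0.00763 or 0.0523 depending on that reading.

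**Figure D3:**
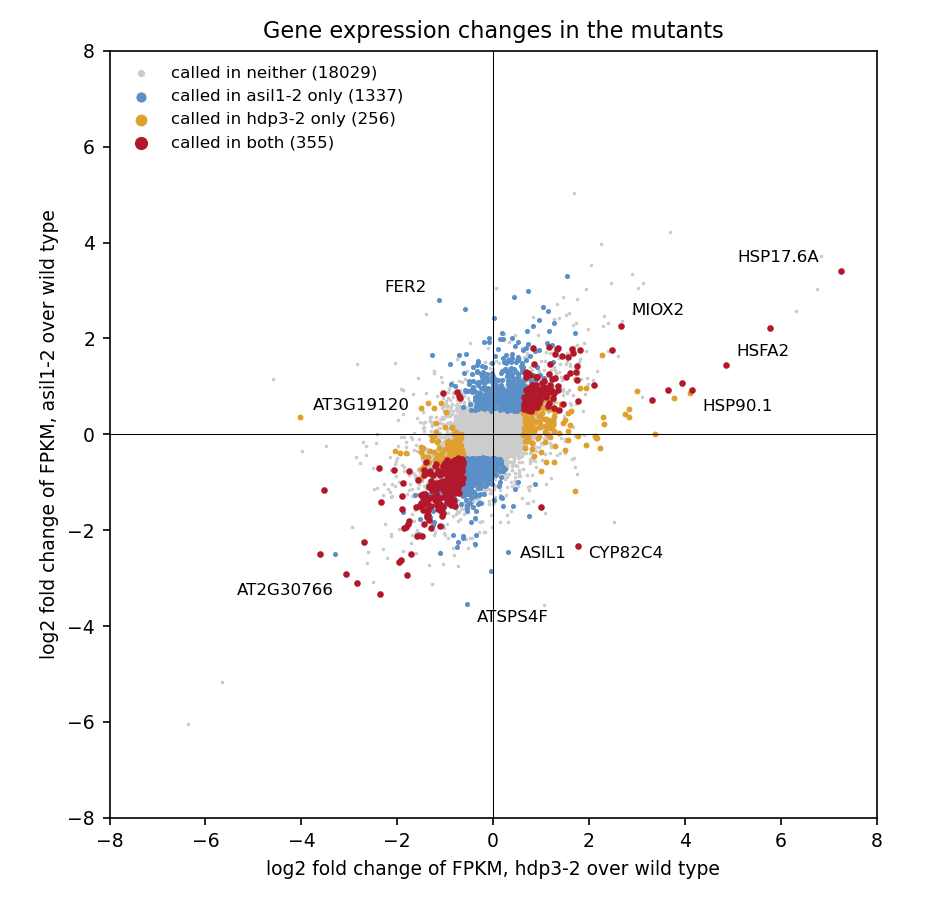
Log2 fold change of FPKM over wild type in hdp3-2 (horizontal axis) and asil1-2 (vertical axis) for 19977 genes tested in both and above 0 in every genotype, with 1 gene beyond the axes. Colours mark the calls, and the 355 genes called in both lie almost wholly in the quadrants of equal direction, with HSP17.6A far to the upper right, while ASIL1, ATSPS4F and AT3G19120 lie near an axis.

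Whether the effects of the mutants differ was tested for each of 19977 genes by a z test on the difference of the log2 fold changes, hdp3-2 minus asil1-2, and 26 genes passed an adjusted p of 0.05. The test is a normal approximation built on the statistics of the authors, with 2 libraries per mutant, and no exact test could be made without values per library. Of these 21 were higher in hdp3-2 relative to asil1-2, and they include the heat shock genes HSP90.1, HSP70, HSP101, HSFA2 and AT1G07400. Also among them were AT2G29500, AT1G54050 and AT5G51440, of the HSP20-like chaperone family. AT3G09440, AT2G20560 and AT5G23240, annotated as heat shock proteins, were there too. These further genes were picked out after their values were seen. By this z test on the authors' statistics HSP90.1 differed by 3.23 ± 0.41 (SE, adjusted p = 5.02e-11), FKBP65 by 2.72 ± 0.41 (adjusted p = 1.56e-07) and HSP70 by 2.47 ± 0.38 (adjusted p = 2.78e-07). By the same z test on the authors' statistics ATSPS4F differed by 2.98 ± 0.38 (adjusted p = 5.02e-11), with a value of -0.56 ± 0.28 in hdp3-2, which was not called, and ASIL1 by 2.76 ± 0.42 (adjusted p = 1.46e-07). The 5 genes on the other side of the z test on the authors' statistics were AT3G19120, at a difference of -4.39 ± 0.57 (adjusted p = 8.72e-11), FER2, at -3.93 ± 0.90, AT5G04120, a phosphoglycerate mutase family gene, at -2.41 ± 0.60, AT1G01920, a SET domain gene, at -1.88 ± 0.44, and AT4G18440, at -1.63 ± 0.37. No gene of the touch, wound and handling list passed, and ZAT10 had an adjusted p of 0.0550 by the z test on the authors' statistics, and with the summed variance multiplied by 0.5, 2 were lower in hdp3-2.

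Of the 6 genes called in opposite directions, 3 passed this test. CYP82C4 (AT4G31940), a cytochrome P450 gene, rose by 1.77 ± 0.52 in hdp3-2 and fell by 2.33 in asil1-2 (SE 0.74), and UGT74E2 (AT1G05680), a glycosyltransferase gene, rose by 1.00 ± 0.31 and fell by 1.51 (SE 0.34). AT4G18440 had -0.74 ± 0.28 in hdp3-2 and 0.88 ± 0.24 in asil1-2. With the normal reading of the authors' statistic all 6 lost their call in hdp3-2 (adjusted p from 0.0787 to 0.696). By the z test on the authors' statistics AT5G26800 did not pass (adjusted p = 0.219), nor did CS26 (AT3G03630) and AT3G25805, which were chosen after their values were seen (adjusted p = 0.0844 and 0.147). With the summed variance multiplied by 0.5, 125 genes passed, 56 higher and 69 lower in hdp3-2, and these 3 genes were among them (adjusted p = 0.000376, 4.46e-05 and 0.000149 on the authors' statistics). At the full variance 344 genes had an unadjusted p under 0.05 where chance alone would give 999, so the test was conservative. The shared wild type and standard errors larger than the authors' p implies would both act this way, and they were not separated.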

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

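The z test of the difference and the count of shared calls were planned, while the tests of the clock, heat shock, touch and photosynthesis genes, the reading of the simulated number of shared calls as a test of chance, and the run without the heat shock, clock and touch lists were chosen only after the result was seen, as was the interval used to judge the test of RNA without a poly(A) tail.

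The z test of the difference between the mutants singled out 26 genes. CYP82C4 and UGT74E2 were called in opposite directions, with differences, hdp3-2 minus asil1-2, of 4.101 and 2.51 in log2. AT4G18440, also called in opposite directions, differed by -1.63. HSP90.1, FKBP65 and HSP70 were higher in hdp3-2 by 3.23, 2.72 and 2.47. ATSPS4F and ASIL1, which fell in asil1-2, differed by 2.98 and 2.76. On the other side AT3G19120 differed by -4.39, FER2 by -3.93, AT5G04120 by -2.41 and AT1G01920 by -1.88.

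The first pattern is the calls shared by both mutants. Simulated mutants without an effect, sharing chance values of the wild-type libraries, reached at most 195 shared genes in lists of the observed sizes against 349 observed (at most 1 against 70 under the normal reading of the statistic), but the simulation leaves out any way in which the wild-type plants differed from both mutants, such as day of harvest, so it does not decide. Wild-type plants harvested at another time of day could give clock changes of equal direction in both mutants, and 100% of the 10 clock genes called in both had the same direction. This decides nothing, since a shared effect of HDP3 and ASIL1 predicts the same and the shared wild type alone gives it for nearly any gene called in both, with 0.629 genes in opposite directions on average in the simulations, so these cannot be told apart without values per library. Leaving out the heat shock, clock and touch lists left 333 shared genes. These lists hold only 14, 24 and 16 genes, so the count could fall little and decides nothing about these explanations.

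The second pattern is the heat shock genes higher in hdp3-2. A low heat shock level in the shared wild-type libraries would raise them equally in both mutants, and 5 of the 8 called genes differed between the mutants, which argues against it as the whole cause. Of the 7 with a difference, all 7 were higher in hdp3-2, with a median of 3.23. The genes were taken because they were called higher in hdp3-2, which favours this direction and a larger median there. Warming or handling of the hdp3-2 plants before harvest may account for part of it and stays open, since it is confounded with genotype: 3 of 15 touch and handling genes rose there and TCH2 fell, but 9 of 15 rose in asil1-2, where the median of the 7 heat shock genes was 1.07 against 4.15 in hdp3-2. An effect of the mutation stays open as well, untested.

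The third pattern is the organelle transcripts higher in hdp3-2, for which no biological explanation was tested. A larger share of green tissue would raise nuclear photosynthesis genes too, but their median log2 fold change was -0.14 over 28 genes, below the lower quartile of the plastid genes, 0.62, which argues against it. More RNA without a poly(A) tail in the hdp3-2 libraries may be a source: 50% of the nuclear snoRNA, snRNA, rRNA and tRNA genes that could be measured were positive, but these were 4 genes, with an exact 95% interval from 6.76% to 93.2%, too few to decide. The FPKM sum in the authors' deposited table, 4.47e+06 in hdp3-2 against 1.46e+06 in wild type, moves with the pattern, but its highest value belongs to a plastid gene, so it is not independent evidence. The prediction written beforehand took 50% or less as evidence against, without asking how many genes there would be.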

How the results depend on the processing

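The normal reading of the authors' statistic and the runs without the heat shock, clock and touch lists were chosen after seeing the data, as were the pseudocount and centring for ASIL1 and the other named genes. Called genes in hdp3-2 (622) became 341 at q under 0.01, 274 with a minimum log2 fold change of 1, 210 with that minimum and a pseudocount of 1, 273 with it after centring, and 147 with the normal reading. In asil1-2 (1702) these counts were 918, 453, 295, 439 and 438. Shared calls in the same direction (351) became 201 at q under 0.01, 107 with the minimum fold and 70 with the normal reading. The settings of q and fold are stricter by construction, but the normal reading is not. It gives larger p-values for most genes, because the authors' p is mostly smaller than their statistic implies. It can also add genes. HSP17.6II (AT5G12020) in hdp3-2, chosen after its value was seen, had a statistic of 6.09 but a p of 0.090 in the authors' Cuffdiff test. The other settings gave 599 to 634, 1673 to 1718 and 333 to 351. Pearson's r (0.53) was 0.52 and 0.55 with pseudocounts of 1 and 0.1, 0.58 at FPKM of at least 10, 0.51 with no minimum and 0.63 over called genes. The cause of these shifts was not tested. Genes that differ between the mutants (26) numbered 125 with the summed variance multiplied by 0.5, which also made false calls in simulated data. ASIL1 in asil1-2 kept its direction, at -2.21 with a pseudocount and -2.38 after centring. Of 12 enrichments, counted per list, direction and mutant, 4 were lost with the minimum fold and 3 at q under 0.01. Enrichments gained under these settings are not in this count. Of the 122 called values of named genes, 48 lost their call with the normal reading and 34 at q under 0.01. None reversed. No paired analysis was possible because the tables hold no values per library, and leaving out each replicate was not run for the same reason. Depth is not given, so what it limits is unknown.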

Other observations

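The test of AT3G19120 was chosen only after its value was seen, as were the copper genes.

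The following 3 genes form no fixed list and were not tested as a group. In hdp3-2 CSD2 (AT2G28190), a copper and zinc superoxide dismutase, had a log2 fold change of -2.08 ± 0.28 (SE), CCS (AT1G12520), the chaperone that loads copper into it, -1.32 ± 0.28, and CSD1 (AT1G08830) -0.96 ± 0.29. In asil1-2 CSD2 and CCS fell as well, at -0.74 ± 0.24 and -0.76 ± 0.24, and CSD1 was not called, at -0.20 ± 0.25. The difference between the mutants did not pass for CSD2 (-1.33 ± 0.37), and passed with the summed variance multiplied by 0.5.

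Of 6 genes whose entry in the reference names Harbinger or the PIF and Ping-Pong family, AT2G13770 and AT5G35695 were listed at 0 in every genotype. AT3G55350, AT3G63270 and AT5G41980 were called in neither mutant, with log2 fold changes in hdp3-2 of -0.11, 0.07 and -0.51. Of these 6, AT3G19120 was called, in hdp3-2. AT4G29780, of the fixed Harbinger list, is annotated as a nuclease without those names and is not among the 6.

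A hypothesis is that AT3G19120 may be the gene disrupted in hdp3-2, since it fell there and its log2 fold change in hdp3-2 minus that in asil1-2 was -4.39 ± 0.57 (SE). A gene that merely depends on HDP3 would give the same value, and no source used here pairs HDP3 with a locus, so this stays open.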
